A study of Drosophila melanogaster with 3 samples.

How the data were processed

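Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the CG5245 protein contacts the genome of Drosophila melanogaster embryos. Per the labels, the flies carried a transgene in which CG5245 is fused at its C terminus to enhanced green fluorescent protein, and chromatin was pulled down with an antibody against that tag. The description in the labels names this antibody, whereas their antibody field reads CG5245, and the description was followed. Whole embryos of both sexes aged 0 to 16 h were collected, and chromatin was sheared by sonication to fragments of 200 to 800 bp. The labels describe 3 biological replicates of this 1 group and a shared control, which was not analysed here. No other genotype or stage was part of the data, so no contrast between groups was made.

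The deposited files were lists of genomic regions, each with a position, a summit, a signal value and a q value. Per the text files deposited beside the lists, the authors derived candidate regions from each replicate with the control and from the 3 replicates together with it. From these they derived a reproducible set with the irreproducible discovery rate (IDR), a measure based on how alike regions rank across replicates. The aligner, the peak caller and their settings are not given in the sources used here. The signal value of a region is a score that the authors' peak caller gave to it, taken here as deposited and used only to rank or filter regions within a list. The q values were deposited as −log10 values, and within the reproducible set every peak had the same one, 3.88. Lists were deposited on the assemblies dm6 and dm3. The dm6 lists gave all main results, and dm3 coordinates were not converted. No file gives read counts, so the sequencing depth of each replicate is unknown, and no interval that needs it is given.

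The reproducible set held 3670 peaks on dm6, which were the 3670 pooled candidates of highest signal. The candidate lists held 30000 regions for the pool, 30000 each for replicates 1 and 2, and 29608 for replicate 3. For comparisons between replicates each list was reduced to its 3670 regions of highest signal, called top regions below. Candidates that overlapped no peak of the reproducible set (25710 regions) served as background called by the same procedure, and the 3670 lowest-ranked of them as a stricter background.

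Gene models were those of Ensembl release 115 on Release 6 of the fly genome, restricted to the 6 main chromosome arms, with 18164 genes and 23581 distinct transcription start sites (TSSs). The sequence was the matching Release 6 assembly. A summit within 500 bp of a TSS was called promoter, and other summits were called exon, intron or intergenic in that order. A gene was called occupied when a summit lay within 500 bp of a TSS of any of its transcripts.

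Overlap of replicates (at least 1 bp) and location were tested against 1000 random placements of summits within their chromosome arm, 2-sided, for which the smallest possible p is 0.002. Occupancy of 24 gene lists was tested with Fisher's exact test against the other protein-coding genes, or against all genes for small RNA genes. Sequence motifs within 50 bp of the summit were compared with a window of the same size 500 bp away in the same peak by the exact McNemar test, for 16 motifs. Words of 8 bases were searched on arms 2L, 2R and X and tested on 3L, 3R and 4. Chromosome arms were compared by Fisher's exact test with the candidates outside the reproducible set, and correlations across peaks used 100000 permutations. Peaks are not independent replicates, so p-values across peaks describe these lists. Adjusted p-values are Benjamini-Hochberg values over the lists, motifs, words, arms or relations tested together, with a threshold of 0.05. Values with a standard deviation (SD) were computed on the top regions of each replicate, n = 3.

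Gene lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named CG5245 and the genes whose TSS lay nearest, within 500 bp, to the 15 strongest peaks that overlap top regions of all 3 replicates. It also named up to 4 occupied genes of highest signal from each list with an adjusted p under 0.05 and, in any case, from the Hox, segmentation, neural and insulator lists. Motifs were named where the adjusted p was under 0.05 and the share of peaks over 10%. Any other gene or motif in the text was chosen after its values were seen. Older gene symbols were matched to current ones, and 2 of the 8 dosage compensation genes, which are non-coding, were left out of the test against protein-coding genes.

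The tests were tried on simulated data of the same size. The promoter test called 20 of 20 sets whose promoter share had been raised, by a mean of 8.76 percentage points, and 0 of 20 random sets. The list test called 56 of 60 lists of 30 genes occupied 3 times as often as other genes, and 0 of 240 random lists. The motif test called 10 of 10 sets with a word planted in 183 of the 3670 peaks and 0 of 10 random sets. The search for words of 8 bases ranked the planted word at the top in 3 of 3 sets and called none in 3 random sets. The motif and word simulations used random positions, where the window and its flank differ little in A and T content (0.364 percentage points). At the real summits this difference was 7.96 points. The simulations therefore do not show how many motifs or words such a difference alone would call. Alternatives covered the promoter window, the number of top regions, the definition of overlap, the background, the motif window and flank, word length, assembly and leaving out each replicate. For gene lists, leaving out a replicate kept only top regions shared by the others. That list was shorter than the full set, so a lower excess or a lost call need not reflect the replicate left out. Comparisons with random draws of genes in the same class of TSS number (4 classes, 10000 draws), with shuffled summit sequences and without the histone genes were added after the data were seen. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.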

Results

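The data describe a single group of embryos in which CG5245 carried a C-terminal green fluorescent protein tag. They consist of peak lists from 3 biological replicates, a pooled list and the authors' reproducible set. CG5245 encodes a protein with zinc fingers of the C2H2 type, a fold found in many sequence-specific DNA-binding proteins. The comparisons implied by this design are between replicates, and between the bound regions and the rest of the genome. Sequencing depth is unknown, because the lists hold no read counts.

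CG5245 was found at 3670 reproducible sites on the dm6 assembly. Their median width was 396 bp, and together they covered 1267669 bp, or 0.947% of the main chromosome arms. Exactly this width was given to 2812 of them (76.6%) and to 97.1% of the pooled candidates. Neither width nor coverage therefore measures the extent of binding. Of the 3670 entries, 5 repeated the interval of another. Signal values, which are the authors' own, ranged from 92.4 to 2002 with a median of 147.6, so a few sites stood far above the rest. Of the 3670 peaks, 2440 (66.5%) overlapped top regions in all 3 replicates, 852 in exactly 2, 361 in 1 and 17 in none. All 100 of the strongest peaks were among the top regions of every replicate. Pairs of replicates shared 77.8%, 73.4% and 75.1% of their top regions (75.4% ± 2.23, SD of the 3 pairs). Random placement gave a mean overlap of 1.97% to 2.01% (p = 0.002 for each pair, 2-sided permutation test, the smallest value 1000 placements allow). Across the reproducible peaks the signals of replicates 1 and 2 correlated with a Spearman rho of 0.755, those of 1 and 3 with 0.680 and those of 2 and 3 with 0.748. The set was the 3670 pooled candidates of highest signal, from the same 3 replicates. Its overlap with their top regions and these correlations therefore describe it and are no test of reproducibility. The overlaps between pairs of replicates used each replicate's own top regions. Under a stricter definition (signal over the median of the set and top regions in all 3 replicates) 1779 peaks remained.

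The tagged gene itself was not a reproducible target. CG5245 (FBgn0038047) lies on chromosome 3R from 12429560 to 12431235 on the plus strand of dm6. No reproducible peak had its summit in the gene or within 500 bp of its TSS, and the nearest summit, at 12434027, lay 2792 bp away with rank 1339. Weak candidate regions did lie in the gene. The best of them ranked 7929 in the pooled list, 5201 in replicate 1, 22969 in replicate 2 and 7573 in replicate 3. Within 20 kb of the gene replicate 1 had 23 candidate regions, above 95.2% of other protein-coding genes, whereas replicates 2 and 3 had 16 each and the pooled list 11, the median of other genes.

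The strongest binding was at promoters of genes with varied cellular roles. Of the 15 strongest peaks, 11 lay in promoters, 3 in introns and 1 between genes, and none ranked below 21 in any replicate. The peak of highest signal (2002, X from 2703682 to 2704088) had its summit 35 bp from the TSS of Ugalt, which encodes a UDP-galactose transporter, and ranked 1 in each replicate. A peak with a signal of 1759 on 3L, from 19590428 to 19590814, lay 96 bp from the TSS of CG14100. Chro, which encodes the chromatin protein Chromator, had a peak of signal 1410 whose summit at 22878879 on 3L lay in an exon, 105 bp from the TSS. An internal TSS of ph-p, which encodes a subunit of the Polycomb repressive complex PRC1, lay 480 bp from a summit of signal 1368 on X at 2137335. The remaining promoter peaks of this group were nearest to px, Art3, CenG1A, PNPase, mRpL41, CHMP2B and CG1888. Art3 encodes an arginine methyltransferase, PNPase an RNA exonuclease of mitochondria, mRpL41 a mitochondrial ribosomal protein and CHMP2B a component of the ESCRT-III membrane complex. Their signals ranged from 1072 (CG1888) to 1579 (px). The 3 intronic peaks lay in ush (signal 1691, on 2L from 480888 to 481288), CG11050 (1365) and Lk6 (1171), and the intergenic one on 3R from 16222300 to 16222670 (1096). The genes at these 4 peaks fall outside the naming rule and were chosen after their values were seen.

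CG5245 sites were concentrated at promoters. In the reproducible set 1799 summits (49.0%) lay within 500 bp of a TSS, and the top regions of the replicates gave 48.9% ± 2.41 (SD, n = 3). Random placement put 13.6% of summits there, a difference of 3.62-fold (p = 0.002, 2-sided permutation test), and the lowest-ranked candidates had 17.9% (odds ratio 4.40, p = 5.5e-180, Fisher's exact test). Among all candidates outside the reproducible set the share was 26.4%, so the contrast was smaller (ratio of shares 1.85, p = 3.1e-161, Fisher's exact test). Exons outside promoters were nearly free of summits, with 2.32% against 19.8% under random placement and 15.7% in the lowest-ranked candidates. Introns held 33.8% of summits against 39.5%, and intergenic sequence 14.9% against 27.2%, each with p = 0.002 in the permutation test. The classes exclude each other and promoters were assigned first, so a high promoter share lowers the other shares. The lower intron and intergenic shares are therefore no evidence that these sequences were avoided. Of the 1871 summits outside promoters, 1240 lay in introns, 546 between genes and 85 in exons, and this split was not tested. Within promoters the summits sat upstream of the TSS: 1479 were upstream and 317 downstream (82.3% upstream, p = 4.6e-179, exact binomial test), at a median of -95 bp. The lowest-ranked candidates in promoters were upstream in 51.0% of cases (p = 0.640, exact binomial test), with a median of -5 bp.

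**Figure D1:**
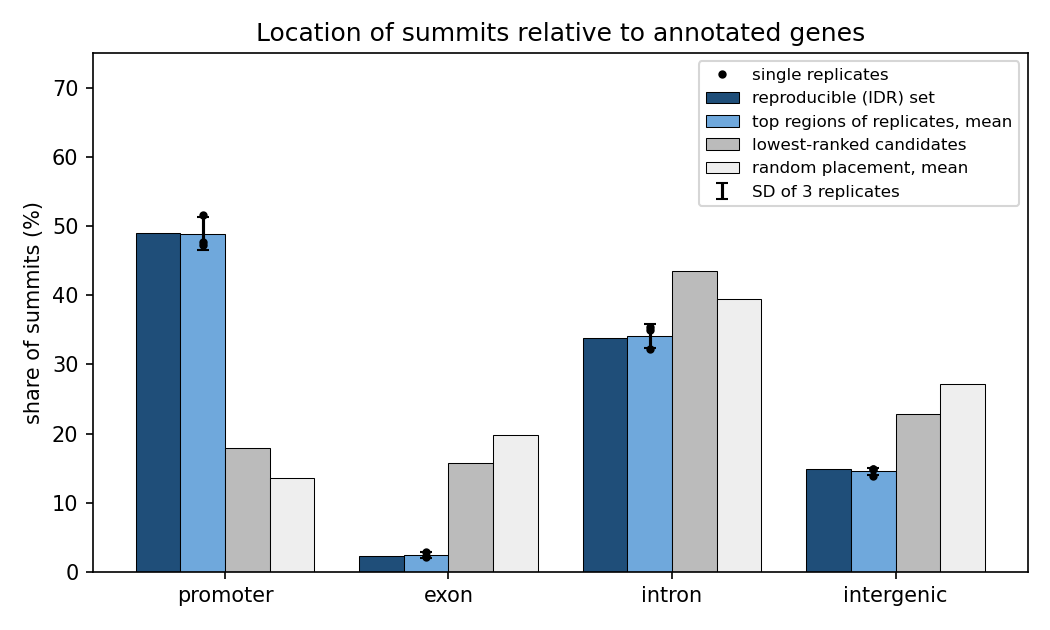
Share of summits in promoters, exons, introns and intergenic sequence (vertical axis, %), for the reproducible set, the mean of the top regions of 3 replicates (error bar SD, points single replicates), the lowest-ranked candidates and random placement. Promoters hold 49.0% of the reproducible summits against 17.9% in the lowest-ranked candidates and 13.6% under random placement.

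**Figure D2:**
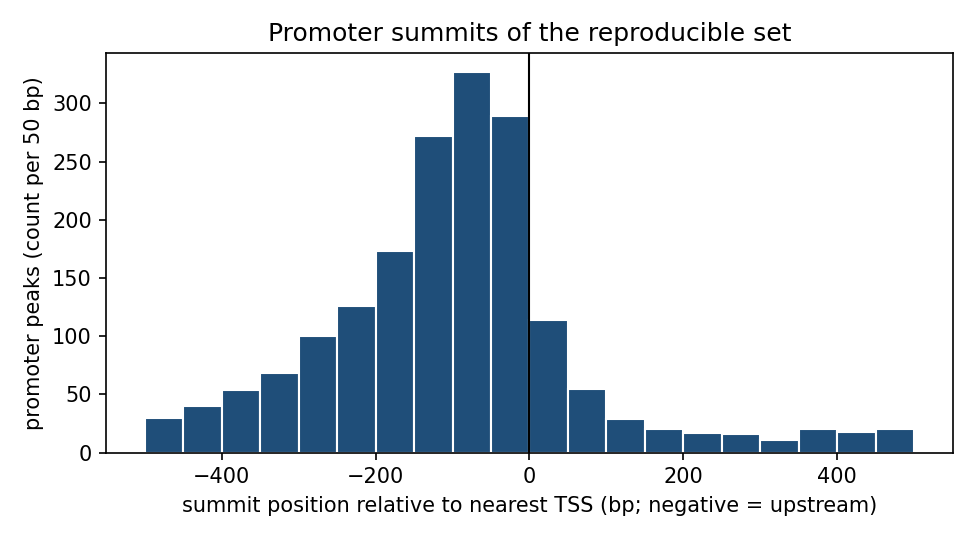
Number of promoter peaks of the reproducible set (vertical axis, count per 50 bp) by the position of the summit relative to the nearest TSS (horizontal axis, bp, negative values upstream). Most summits, 1479 of 1799, lie upstream, with a median of -95 bp.

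Cytoplasmic ribosomal protein genes, which encode the ribosome's structural proteins, had the highest occupied share of the 24 lists. Of all 13945 protein-coding genes, 2210 (15.8%) were occupied, and 15.7% ± 0.728 (SD, n = 3) in the top regions of the replicates. Among cytoplasmic ribosomal protein genes, 59 of 93 (63.4%) were occupied, against 15.5% of other protein-coding genes (adjusted p = 8.0e-24, Fisher's exact test). The share was 57.0% ± 10.3 (SD, n = 3) in the top regions of the replicates. The excess of 47.9 percentage points was 30.3 without replicate 1, 31.3 without replicate 2 and 43.7 without replicate 3, and passed the threshold each time. RpS27, RpL7, RpL41 and RpL32 had the highest signals of this list, at 563, 540, 370 and 360, with summits 16 to 164 bp from a TSS. Mitochondrial ribosomal protein genes were occupied in 22 of 73 cases (30.1%, adjusted p = 0.00928, Fisher's exact test). They included mRpS10, mRpS23, mRpL41 and mRpL23, with signals of 1335, 1213, 1150 and 739. The peaks at mRpS10 and mRpS23 were nearer to the TSSs of their neighbours Art3 and CenG1A. With each peak given only to the gene of its nearest TSS, the mitochondrial list was occupied 4.31 percentage points less often than other genes (adjusted p = 0.621, Fisher's exact test). Its excess of 14.4 points was 10.2 without replicate 1, 7.33 without replicate 2 and 10.8 without replicate 3 (adjusted p = 0.0763, 0.179 and 0.0551, Fisher's exact test). Translation factor genes were occupied in 17 of 54 cases (31.5%, adjusted p = 0.0164, Fisher's exact test), with eIF6 (816), eIF4EHP (447), eEF1gamma (287) and eIF3c (261) at the highest signals. Their excess over other genes, 15.7 percentage points, was 3.03 without replicate 1, 6.65 without replicate 2 and 11.6 without replicate 3 (adjusted p = 0.836, 0.332 and 0.0819, Fisher's exact test), in the top regions shared by the remaining replicates.

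Genes for chromosomal architectural proteins and for Notch signalling were also occupied more often than other genes, with calls that several alternatives ended. The insulator and architectural protein list had 7 of 18 genes occupied (38.9%, adjusted p = 0.0474, Fisher's exact test). The call was lost when the histone genes were left out (adjusted p = 0.0541, the same exact test). It was also lost without replicate 1 or 3, where the excess of 23.1 percentage points became 16.0 and 15.2. Among genes with a candidate region the list was 10.2 points above other genes (adjusted p = 0.801, Fisher's exact test). Of the alternatives tried, only leaving out replicate 2 kept the call (27.0 points, adjusted p = 0.0154, the same exact test). Its strongest members were Chro (1410), Cp190 (360), which encodes a cofactor shared by several insulator proteins, Trl (223), which encodes the GAGA factor, and M1BP (221), which encodes a core promoter factor. The Notch and E(spl) list had 8 of 21 genes occupied (38.1%, adjusted p = 0.0395, Fisher's exact test). E(spl)m3-HLH (287), numb (279), which encodes an inhibitor of Notch, E(spl)mdelta-HLH (179) and E(spl)m7-HLH (150) had the highest signals. The excess of this list, 22.3 percentage points, was 16.0 to 16.8 without any 1 replicate, and the call was lost each time. It was 10.5 with the upper 50% of peaks by signal and 9.05 among genes with a candidate region (adjusted p = 0.345 and 0.801, Fisher's exact test). Of the 5 lists occupied more often, only the cytoplasmic ribosomal protein list passed the threshold under all alternatives tried, which the closing section lists. With the upper 50% of peaks by signal, or with peaks in the top regions of all 3 replicates, it was the only list of the 5 that did.

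Apart from the Notch and E(spl) list, no list of developmental genes passed the threshold. These lists were small, and the simulations covered only lists of 30 genes at 3-fold occupancy. None of the 8 Hox genes was occupied (adjusted p = 0.905, Fisher's exact test), although 7 of them had a candidate region within 500 bp of a TSS. Segmentation genes were occupied in 2 of 22 cases (9.09%, adjusted p = 0.905, Fisher's exact test), namely hry, the current symbol of hairy (344), and bcd (306). Neural genes were occupied in 2 of 22 cases (9.09%, adjusted p = 0.905, Fisher's exact test), with elav (475), which encodes a neuronal RNA-binding protein, and pros. The peak at pros ranked 3212 and was in the top regions of 1 replicate only. The counts were 2 of 19 for dorsoventral patterning, 2 of 9 for glial, 6 of 22 for mesoderm and muscle, 2 of 13 for epidermis, cuticle and trachea, and 1 of 14 for gut, fat body, hemocyte and salivary gland genes. Among the signalling pathway genes 4 of 30 were occupied, and among the germline and piRNA pathway genes 4 of 23. The adjusted p-values of these 7 lists ran from 0.316 to 1. Polycomb and Trithorax group genes (9 of 28, adjusted p = 0.0781) and cell cycle and replication genes (11 of 36, adjusted p = 0.0588) did not pass the threshold of Fisher's exact test. The Polycomb and Trithorax list passed with the nearest TSS only (21.0 percentage points above other genes, adjusted p = 0.0119) and without replicate 2 (16.7, adjusted p = 0.047), and the cell cycle list without replicate 2 (15.9, adjusted p = 0.0304), by the same exact test. Proteasome genes had 7 of 48 occupied, oxidative phosphorylation genes 13 of 87, heat shock and chaperone genes 7 of 34 and dosage compensation genes 0 of 6. None of these lists passed the threshold, with adjusted p-values of 1, 1, 0.905 and 0.905 by Fisher's exact test. With only 6 genes the dosage compensation list can show little.

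Genes for tRNAs, the adaptors of translation, were occupied less often than other genes. Of 290 tRNA genes, 14 (4.83%) were occupied against 13.4% of all other genes (adjusted p = 2.3e-05, Fisher's exact test). The highest signals were at tRNA:Tyr-GTA-1-8 (492), tRNA:His-GTG-1-3 (201), tRNA:Trp-CCA-2-2 (147) and tRNA:Leu-TAA-2-1 (141). Most of the other genes are protein-coding, and 15.8% of protein-coding genes were occupied. Of 3261 genes annotated as ncRNA, 158 (4.85%) were occupied, so the low share was not particular to tRNA genes. Random draws of genes with as many TSSs as the tRNA genes had 9.98% occupied. Of 301 snRNA and snoRNA genes, tested as 1 list, 19 (6.31%) were occupied (adjusted p = 0.000868, Fisher's exact test). The list joined 13 of 269 snoRNA genes (4.83%) with 6 of 32 snRNA genes (18.8%, above the 13.2% of all genes), and these classes were not tested apart. A peak of signal 371 lay within 500 bp of both snoRNA:Or-aca5 and snoRNA:Psi28S-2949, and a peak of signal 294 did so for snRNA:U6:96Ac and snRNA:U6:96Ab. None of the 111 replication-dependent histone genes, which lie in a tandem repeat, was occupied. None of them had a pooled candidate region of any rank within 500 bp of a TSS, against 51.2% of protein-coding genes with one, so the list had nothing to test and absence of binding is not shown. With genes of the same number of TSSs as reference, the snRNA and snoRNA list did not pass the threshold, with 9.97% occupied among such genes drawn at random 10000 times. Nor did it among genes with a candidate region (difference -5.77 percentage points, adjusted p = 0.729, Fisher's exact test), and at 1000 bp its difference changed sign to 1.69 points (adjusted p = 0.647).

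**Figure D3:**
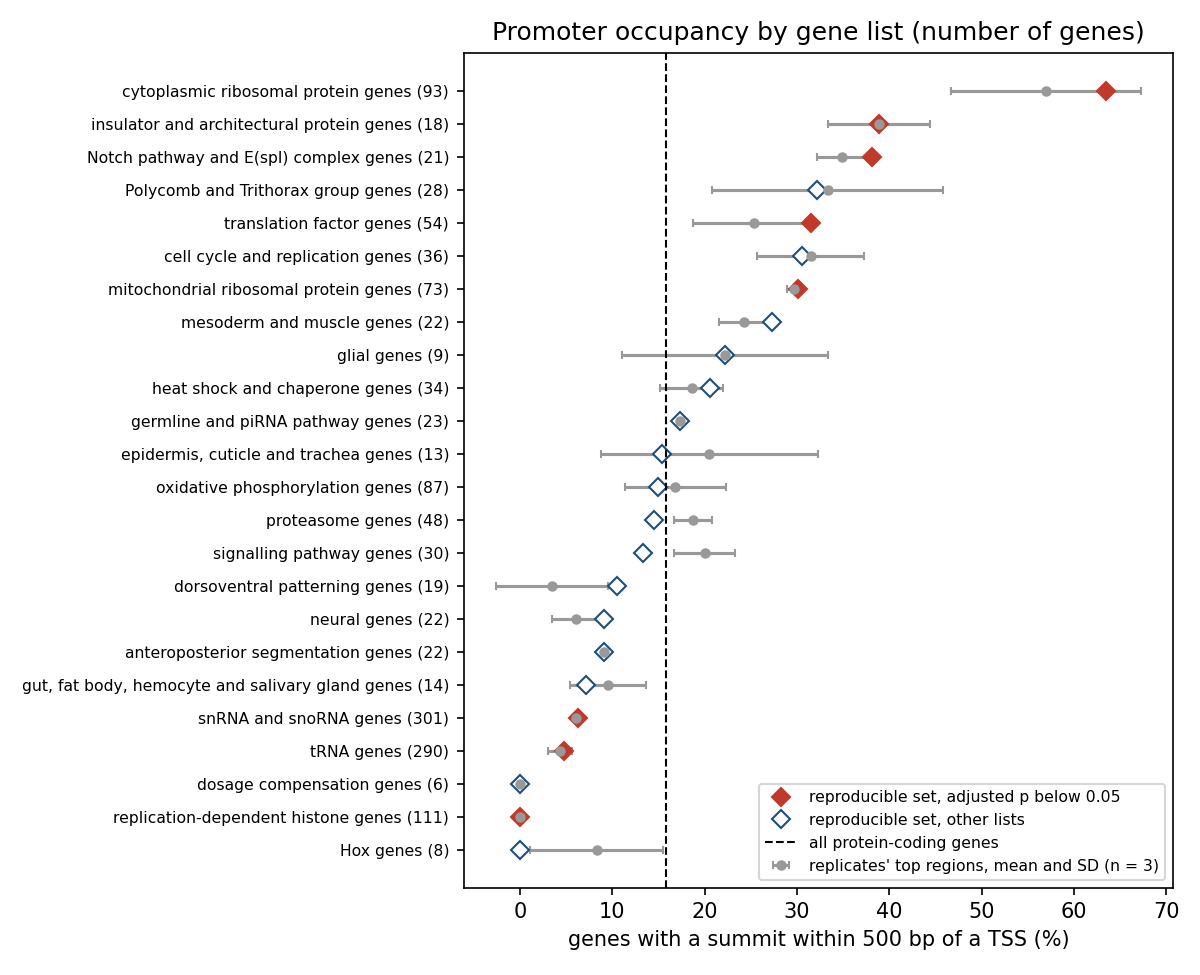
Share of genes with a summit within 500 bp of a TSS (horizontal axis, %) for 24 gene lists (number of genes in brackets). Diamonds show the reproducible set (filled where the adjusted p was below 0.05), grey points and bars the mean and SD of the top regions of 3 replicates, and the dashed line all protein-coding genes, 15.8%. Cytoplasmic ribosomal protein genes stand at 63.4%, and the histone genes, at 0, have no candidate region.

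The DNA at the summits was rich in A and T. Within 50 bp of the summit 64.4% of bases were A or T, against 56.4% in the window 500 bp away, a difference of 7.96 percentage points. The difference was 7.56 ± 0.629 points (SD, n = 3) in the top regions of the replicates. The summit was richer than its flank in 2645 peaks and poorer in 957 (p = 9.7e-181, exact sign test). Peaks in promoters (8.44 points) and outside them (7.49 points) both showed it. The lowest-ranked candidates did not, with 57.9% at the summit and 58.6% in the flank.

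**Figure D4:**
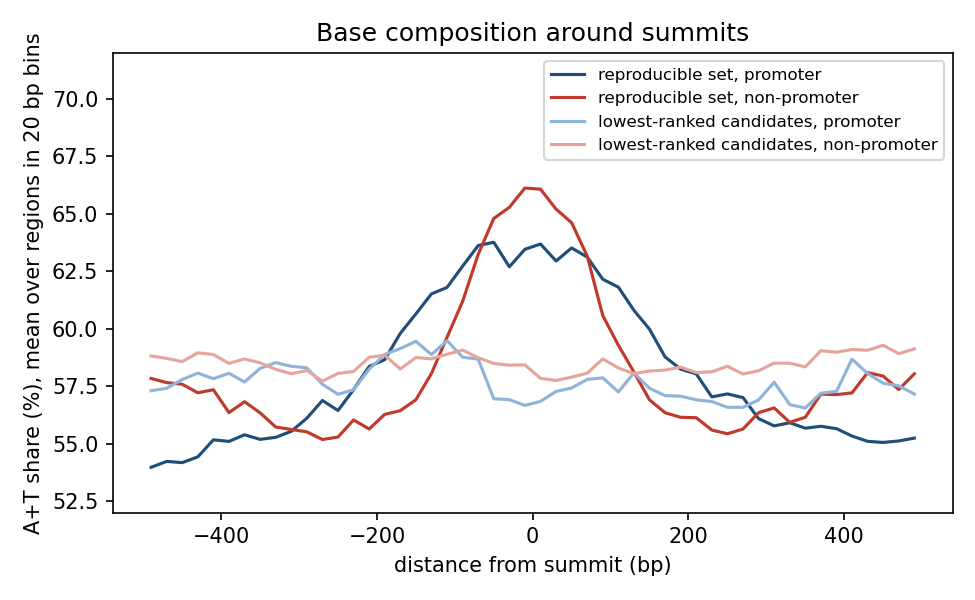
Share of A and T bases (vertical axis, %, mean over regions in 20 bp bins) by distance from the summit (horizontal axis, bp), for promoter and non-promoter regions of the reproducible set and of the lowest-ranked candidates. The reproducible set rises to 66.1% at non-promoter summits and to 63.8% near promoter summits, and the lowest-ranked candidates show no such rise.

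Of the 16 motifs tested, 9 were more frequent at summits than in flanks, 4 were less frequent and 3 showed no called difference. Against shuffled summits 6 of the 9 were also more frequent. Of the 4, GAGA (adjusted p = 9.7e-07), CAGCTG (5.7e-08) and the CA repeat (1.5e-05) were more frequent at summits than in shuffled summits (exact McNemar tests). Shuffled summits held them at 0.272%, 1.85% and 0.381%, and flanks, which were not shuffled, at 2.10%, 5.12% and 3.11%. The flanks were further above the shuffled sequences than the summits were. These calls therefore do not oppose the lower share at summits than in flanks. The BEAF-32 motif CGATA, bound by the insulator protein of that name, occurred at 16.6% of summits and 11.3% of flanks (adjusted p = 8.9e-10, exact McNemar test). The log2 ratio of summits to flanks was 1.07 in promoter peaks (adjusted p = 1.4e-19) and -0.12 outside promoters (adjusted p = 0.509, exact McNemar tests), and the difference between these ratios was not tested. In the top regions of the replicates the motif occurred at 15.9% ± 1.29 of summits (SD, n = 3). The GATA motif occurred at 20.5% of summits and 16.4% of flanks (adjusted p = 1.9e-05, exact McNemar test). Against summit sequences shuffled to keep their dinucleotide content, GATA was less frequent (23.7% in the shuffled sequences, adjusted p = 0.00105, exact McNemar test), whereas BEAF-32 was still more frequent (11.1%, adjusted p = 2.5e-12). Rarer motifs, chosen for mention after their values were seen, included Ohler motif 7, a core promoter element, at 3.68% of summits and 0.708% of flanks (adjusted p = 1.4e-18, exact McNemar test). The DNA replication-related element TATCGATA occurred at 1.88% and 0.409% (adjusted p = 1.0e-08), and the CTCF core at 6.27% and 4.06% (adjusted p = 4.6e-05, exact McNemar tests). Outside promoters none of these 3 passed the threshold: the log2 ratio was 1.18 for Ohler motif 7 (adjusted p = 0.0855), 0 for TATCGATA (adjusted p = 1) and 0.45 for the CTCF core (adjusted p = 0.0601), by the same exact test. Zelda sites, by contrast, occurred at 0.463% of both (adjusted p = 1, exact McNemar test).

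No single word described most peaks. Of 13531 words of 8 bases tested on arms 2L, 2R and X, 171 were enriched at summits and 44 depleted. Of the 171, 113 were also enriched on the held-out arms 3L, 3R and 4 at an unadjusted p under 0.05, and 63 of the 171 consisted of A and T only. How many of these words the A and T excess at summits alone would give was not tested. The first by p was TGGCGCCA, at 32 summits and 1 flank among 1991 peaks. On the held-out arms it occurred at 0.715% of summits and 0.179% of flanks (p = 0.0352, exact McNemar test). Allowing 1 mismatch ended the difference, with 3.57% of summits and 3.45% of flanks (p = 0.926, exact McNemar test). CACTGAGA (1.61% and 0.417%), CAACACTG (1.97% and 0.298%) and AGATGGCG (2.08% and 0.536%), which contains the CTCF core, were further enriched words on the held-out arms, with p = 0.000821, 4.3e-06 and 0.000106 by the exact McNemar test. They were chosen after their values were seen. When promoter and other peaks were searched apart, the first words were AAACATTT and TGGCGCCA, and neither passed on the held-out arms (p = 0.0708 and 0.109, exact McNemar test). With the arms exchanged the first word was ATATTAAA (4.02% of held-out summits and 1.51% of flanks, p = 2.0e-06), and with 6 bases it was TTAAAA (31.4% and 13.9%, p = 6.2e-33, exact McNemar tests). Both passed, and both consist of A and T only, unlike TGGCGCCA.

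Chromosome 4, a small and largely heterochromatic chromosome, held few sites. It had 12 of the 3670 reproducible peaks (0.327%), against 1.17% of the candidates outside the set (odds ratio 0.276, adjusted p = 1.0e-06, Fisher's exact test). The share was 0.372% ± 0.0416 (SD, n = 3) in the top regions of the replicates. This is 9.01 peaks per Mb, compared with 25.5 to 29.3 on the other arms. The X chromosome (17.9% against 16.4%, odds ratio 1.11) and 3L (21.6% against 23.3%, odds ratio 0.906) differed slightly, each with an adjusted p of 0.0457. Neither passed the threshold on the dm3 lists (adjusted p = 0.0693 and 0.119, Fisher's exact test). The direction for 3L depended on the reference: relative to its 19.3% of TSSs it held more peaks (log2 ratio 0.16, adjusted p = 0.00141, exact binomial test).

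Stronger peaks lay somewhat nearer to TSSs. Among the 917 peaks of highest signal 55.3% were in promoters (95% Wilson interval 52.1% to 58.5%), against 45.5% (42.3% to 48.7%) among the 919 of lowest signal. The correlation across peaks was small (Spearman rho -0.0477, permutation p = 0.00425, adjusted p = 0.00638 over 3 relations). Signal also rose with the A and T share at the summit (rho 0.0937, permutation p = 1e-05, the smallest possible, adjusted p = 3.0e-05) and showed no detectable relation to the word TGGCGCCA (rho 0.0164, adjusted p = 0.322). Of the strongest 917 peaks, 99.6% were in the top regions of all 3 replicates, and of the weakest 919, 13.7%. The set and the top regions were cut at the same number, so the weakest peaks lie near the cut and a fall is built in. Candidates of any rank in replicates 1, 2 and 3 overlapped 99.9%, 99.9% and 98.8% of the whole set.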

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

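The counts in this part were chosen after the lists had been seen. The dm3 lists include sequences outside the main chromosome arms, which the dm6 lists do not cover and no comparison above used. The pooled dm3 list had 39 candidate regions there, 38 of them on sequence assigned to heterochromatin. Replicate 1 had 61 such regions (55 heterochromatic), replicate 2 had 69 (67) and replicate 3 had 96 (90). A single region of the dm3 reproducible set, ranked 1292, lay on heterochromatic sequence. No control list was analysed here, no dm3 sequence or annotation was at hand to place these regions relative to genes, and no explanation was tested.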

How the results depend on the processing

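Alternatives that used genes of the same TSS number, shuffled summits or no histone genes were chosen only after the data were seen. Of 474 alternatives over 59 results, 339 were scored as unchanged, 70 lost the call, 7 gained it, 36 changed sign and 22 moved a count. For a test, unchanged means the same direction and side of the threshold. Results that are counts have neither, and some scored as unchanged did differ. For example, motifs more frequent at summits went from 9 to 6 against other candidates. Lists occupied more often went from 5 to 4 with the nearest TSS only. The cause was not tested for any change below, unless stated. The replicate overlap (66.7% to 78.7%), the promoter share against random placement (38.7% to 59.3%, set by the window) and the relation of signal with TSS distance passed under every alternative run. So did the cytoplasmic ribosomal protein list (29.3 to 48.3 percentage points above other genes), the tRNA list and chromosome 4. The histone list counts among the 3 occupied less often, but 0 of its genes have a candidate region, so its calls say nothing about stability.

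The stricter definition left 1779 peaks. The number of lists occupied more often, 5, became 3 at 1000 bp, 1 with the upper 50% of peaks by signal, 1 among genes with a candidate region, 1 with peaks in all 3 replicates and 2 against genes with as many TSSs. Leaving out 1 replicate, with top regions shared by the other 2, gave 1 to 4: 1 without replicate 1, 4 without replicate 2 and 1 without replicate 3. The insulator list lost its call without replicate 1 (16.0 percentage points) or 3 (15.2), when the histone genes were left out (22.9) and among genes with a candidate region (10.2). The translation factor (3.03 to 11.6), Notch (16.0 to 16.8) and mitochondrial ribosomal (7.33 to 10.8) lists lost theirs without any 1 replicate, and the Polycomb and cell cycle lists gained one without replicate 2. The Polycomb list also gained one with the nearest TSS only, and the other 4 gains were of the poly(A) tract. Lists occupied less often fell from 3 to 1 among genes with a candidate region. Motifs less frequent at summits, 4, became 1 at 100 bp, 2 with the flank at 1000 bp, 1 in promoter peaks, 1 against shuffled summits and 2 without any 1 replicate. Motifs more frequent, 9, became 2 outside promoters. The 171 enriched words became 328 with 6 bases, 90 in promoter peaks and 19 outside them. The ratio of the first word on held-out arms, 4.0, was 2.1 in promoter peaks (p = 0.0708) and 4.0 outside them (p = 0.109), exact McNemar tests. It passed with the arms exchanged (2.67) and with 6 bases (2.27), each time for another word, of A and T only. The 3 arms that differed became 1 against length and 1 on dm3.

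Differences in share between a list and other genes changed sign as follows, in percentage points. At 1000 bp the epidermis list was at 4.58, signalling at 8.18 and snRNA and snoRNA at 1.69. With the upper 50% of peaks segmentation was at 0.494 and signalling at 1.40. Among genes with a candidate region glial was at -2.41 and germline at -8.78. With the nearest TSS only, epidermis was at 4.25, oxidative phosphorylation at 1.52, signalling at 2.20 and mitochondrial ribosomal at -4.31. For the last, peaks shared with a closer neighbour are taken away by construction. Without 1 replicate the ranges were -1.44 to 10.3 for glial, -4.86 to 3.50 for epidermis, -2.14 to 4.89 for proteasome, -1.46 to 2.41 for oxidative phosphorylation, -0.125 to 2.92 for heat shock and -1.89 to 0.786 for signalling. Of these lists, the snRNA and snoRNA and the mitochondrial ones had passed the threshold.

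Log2 ratios of motifs changed sign against other candidates for su(Hw) (-0.011) and the poly(A) tract (-0.16). They did so in promoter peaks for CACGTG (0.31) and CAGCTG (0.028), and outside promoters for BEAF-32 (-0.12). Against shuffled summits GAGA (2.12), CAGCTG (1.13), the CA repeat (1.77), GATA (-0.21) and the TATA box (-0.12) changed sign, and all but the TATA box passed the threshold in the opposite direction. For GAGA, CAGCTG and the CA repeat the flanks, which were not shuffled, were still further above the shuffled summits. Their change of sign therefore does not oppose their lower share at summits than in flanks. Log2 ratios of arms changed sign against length for 2R (-0.11), 3L (0.043) and 3R (-0.0086), against TSSs for 2L (-0.056), 2R (-0.23, adjusted p = 1.8e-05) and 3L (0.16, adjusted p = 0.00141, exact binomial tests), and on dm3 for 2R (-0.012).

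The dm3 alternative for the tagged gene was not run, because the lists do not give its dm3 position. No paired analysis was possible because the data hold 1 group and no groups are compared. Depth is unknown, so its effect on the number of regions was not measured.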

Other observations

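Except for the tests of promoters and of A and T content on chromosome 4, the tests in this part were chosen only after the results were seen. Promoters shared by a pair of divergent genes were common among the peaks. A peak counted where protein-coding TSSs pointing away from each other both lay within 500 bp of its summit. Of 1697 peaks in promoters of protein-coding genes, 630 (37.1%, 95% Wilson interval 34.9% to 39.4%) lay at divergent pairs, against 1057 of 6043 (17.5%) among the candidates outside the set (p = 1.2e-61, Fisher's exact test). The top regions of the replicates gave 37.2% ± 0.914 (SD, n = 3). In 94.4% of the 630 the summit lay between the TSSs, against 76.2% of the 1057. Such a summit is upstream of both TSSs, so this result and the upstream position of promoter summits are not independent.

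Of 5 further sequences linked to insulator and promoter proteins, 4 were more frequent at summits than in flanks, and paired BEAF-32 sites were not. A long CTCF form, AGRTGGCGC, was at 91 summits, 12 flanks and 3 shuffled summits (adjusted p = 7.1e-16 against flanks, exact McNemar test). It was at 1.78% of promoter summits and 3.15% of others (adjusted p = 0.00977, Fisher's exact test). The shorter CTCF core was compared only with flanks. Its log2 ratio was 0.83 in promoter peaks (adjusted p = 0.000452) and 0.45 outside them (adjusted p = 0.0601, exact McNemar tests). The difference between these ratios was not tested, so an opposite preference of the long form and the core is not shown. The ZIPIC form CAGGGCTG was at 43 summits and 4 flanks (adjusted p = 3.5e-09), and the DREF-like form WATCGATW at 126 and 45 (adjusted p = 4.5e-10, exact McNemar tests). CACTGAG was at 112 summits and 32 flanks (adjusted p = 1.6e-11, exact McNemar test). Paired BEAF-32 sites were at 4 summits and 2 flanks (adjusted p = 0.688, exact McNemar test). These sequences came from words seen in the same peaks, so the p-values are not independent evidence.

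Cytoplasmic ribosomal protein genes differed in occupancy between replicates: 62, 54 and 43 of 93 in replicates 1, 2 and 3, against 22, 21 and 22 of 73 mitochondrial ones. Single genes, chosen after their values were seen, included Hsp27 (signal 710), which encodes a small heat shock protein, phol (581), which encodes a Polycomb recruiter, brm (533), which encodes a chromatin remodeller, and the glial gene moody (519). The gene spanning most peaks, kirre (17), is 394 kb long, or 4.31 peaks per 100 kb. Of the 10 genes with most peaks the densest were CHES-1-like (29.6 per 100 kb) and tara (26.0).

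The A and T excess at summits may come from base-composition bias of libraries or peak calling, or from promoter sequence. The lowest-ranked candidates lacked it, at -0.656 points (95% interval -1.10 to -0.209), so called summits do not all carry an excess. Candidates were ranked by signal, and a bias that raises signal would leave its regions at the top ranks. That value therefore cannot decide on the former. Under the latter peaks outside promoters should lack the excess, but theirs was 7.49 points (6.90 to 8.09). This argues against promoter sequence as the whole cause. No biological explanation was tested, since the data hold 1 group.

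The scarcity of peaks on chromosome 4 could come from low mappability or copy number. Of the candidates outside the set 1.17% lay there (95% interval 1.05% to 1.31%), above its 0.996% of the sequence. Lower signal from either cause would move regions out of the set and into these candidates, so this share cannot decide. Fewer promoters could cause the scarcity too, but among regions in promoters the odds ratio was 0.194 (0.0516 to 0.519, 4 peaks against 77 candidates). Within 5 classes of regional A and T share the Mantel-Haenszel odds ratio was 0.306 (0.171 to 0.546), which argues against base composition as the whole cause. No biological explanation was tested.

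The high occupancy of cytoplasmic ribosomal protein promoters might come from more TSSs per gene, but it was 3.38 times that of genes with as many TSSs in 10000 random draws, which argues against this. ChIP background at strongly transcribed genes is another candidate explanation. Oxidative phosphorylation and proteasome genes were occupied in 14.8% of 135 cases, against 15.9% of other genes (p = 0.813, Fisher's exact test). The files hold no transcript levels to show that these genes match ribosomal protein genes in transcription, so this explanation and specific binding cannot be told apart. No biological explanation was tested.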
